A study of Homo sapiens and Mus musculus with 21 samples.

How the data were processed

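The study removed PCIF1, a cap-associated adenosine N6-methyltransferase, from HEK293T cells, a transformed human embryonic kidney line, and measured 21 libraries in all. The labels give 1 wild-type (WT) and 2 PCIF1 knockout (KO) miCLIP libraries of HEK293T, 2 miCLIP libraries of WT mouse embryonic fibroblasts (MEF), 2 WT and 3 KO libraries each of ribosome-protected fragments and of their input RNA, and 6 SLAM-seq libraries (WT and KO at 0, 6 and 12 h of uridine chase). miCLIP crosslinks an antibody against N6-methyladenosine to RNA, so that reverse transcription leaves substitutions next to methylated adenosines. It reads both m6A inside transcripts and m6Am, the 2'-O-methylated form at the first transcribed base. SLAM-seq labels RNA with 4-thiouridine and follows the loss of the label. Per the labels' protocols, polyadenylated RNA was selected, and libraries were made with a directional RNA kit (input and SLAM-seq) or the miCLIP cloning protocol (miCLIP and ribosome profiling). The labels do not say that replicates were separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

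The submitters' processing notes list BWA 0.7.17, STAR, bedtools, deepTools and the builds GRCh38, hg38 and mm10, without roles. The aligner and counter behind each file are not given in the sources used here. The deposited input and ribosome-protected fragment tables hold whole-number read counts per versioned Ensembl gene, 1 column per library, with nothing normalized. The input table lists 58381 genes. The fragment table lists 785 genes, each with at least 10 counts in both WT libraries. The rule that left those genes is not stated, and its column totals are not library depths. All 5 columns of each table were matched to a sample by title, and 0 columns were left over. The authors' translational efficiency table gives log2 fold changes with standard errors, a mean normalized signal per gene, a test score and raw and adjusted p-values for 765 genes. Per the file headers, its columns carry DESeq2's names. The authors' SLAM-seq table holds 1 KO over WT ratio per Ensembl identifier for 666 identifiers, counted here as genes, per the file headers. CABIN1 is listed under A and again under G starts, with the same ratio. Which quantity was divided is not stated, and values per chase time were not used here. Both of these deposited tables also name each gene's transcript start: m6Am, A, C, G or T.

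Each deposited m6A list holds single DRACH positions with the count of reads carrying the substitution and the number of reads at the position, called per library. Every listed site has at least 2 substituted reads. The authors' strict m6Am list holds 2360 regions with a score per region (2.01 to 5.88), and what the score is relative to is not stated. It is used only to rank regions.

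Gene names came from the reference gene table of GRCh38 and from the deposited class tables. The files pair Ensembl identifiers with names only in those class tables: 1424 of their 1431 entries matched the reference by accession, 73 carried another symbol there, and they name 1407 distinct identifiers. Of these, 1402 are in the input table and 1396 were tested. The RNA level of every other gene stays under its identifier, and the level of PCIF1 itself is not analysed here. A region was named by the gene whose start lies within 50 nt on the same strand, and a site by the 1 gene whose span holds it, without strand. The reference table gives 1 start per gene. Of 503 genes that the authors class as m6Am, 402 (79.9%, exact interval 76.2 to 83.3%) also had a region named in this way, so genes with another start, such as VIM, count as lacking a region in the list tests.

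Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, robust dispersions and the quasi-likelihood F test of KO against WT, with filterByExpr on the input table. The fragment table was tested in full. Translational efficiency was tested as the interaction of genotype and library kind in 1 model over 10 libraries. P-values are two-sided and were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gene lists and the m6Am class were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated. Medians were set against 10000 random lists matched on expression in 20 bins. Shares carry exact Clopper-Pearson intervals at 95%, which cover counting error only, as reads without molecular identifiers are not independent molecules. Medians carry bootstrap intervals from 1000 draws over genes. Correlations of log2 levels between libraries were 0.974 to 0.988 in the input; between the WT fragment libraries the correlation was 0.648. Log2 levels per library are log2 CPM with a prior count of 2. Lists of positions were compared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

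The m6Am genes were meant to be those with a region of the strict list against all other tested genes. Because names were at hand only for the classed genes, the class of the authors' tables was used instead, with the other classed genes as the background. Shares of sites in untranslated and coding parts, retention per chase time and the comparison of mouse with human genes were also planned and not run.

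Genes were named by a rule set before the data were examined: PCIF1, METTL3, METTL14, FTO, YTHDF2 and DCP2; among called genes with all KO libraries on one side of all WT libraries and a mean of at least 5 CPM, the 8 with the largest rise and fall; up to 3 members of each list with the smallest adjusted p; in untested tables, the 5 highest and lowest genes of at least median level; and the 10 best sites of each list. Of called genes that the files do not name, 2 identifiers are printed. RNF213, DICER1 and the other genes said to be chosen afterwards lie outside this rule. A result withheld for evaluation was left out of the text. The lists, also set beforehand, cover m6A and m6Am enzymes and readers, cap methylation and binding, decapping and decay, ribosomal proteins, other TOP mRNAs, the integrated stress response, heat shock, p53 targets, interferon-stimulated genes, nuclear and mitochondrial genes of oxidative phosphorylation, replication-dependent histones, the cell cycle, cholesterol synthesis, and neural, fibroblast, and blood and endothelial markers. Lists of at least 5 tested members entered camera.

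Several choices were made after values had been seen. The test of lists for m6Am regions (Fisher's exact test over 9854 protein-coding genes with an m6A site in any HEK293T library, Benjamini-Hochberg over 13 lists) was added after the shares were known, and lists matched on reads after that. The comparisons with A starts alone, genes of at least 50 counts on average, the classed tables taken apart and the split by input level were also added later. Alternatives chosen beforehand were DESeq2 1.42.0, its size factors in edgeR, other filters, a replicate block, each library left out, other distances and overlaps, and sites with at least the list's median number of substituted reads.

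On simulated counts with 200 changed genes, the RNA fit of 14436 genes recovered 77.1% of genes changed by a log2 of 1 and 97.9% of those changed by 2, with 9 false calls. The fragment fit of 785 genes recovered 27% and 89%, with 4 false calls, and the efficiency fit of 785 genes recovered 62% and 96%, with 7 false calls. In simulated counts without any change, 1000 random lists of 100 genes gave a camera p under 0.05 in 0.5% (RNA), 0.3% (fragments) and 0.8% (efficiency) of lists. Simulated genes vary independently, so these rates do not cover lists whose genes vary together.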

Results

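The data cover where N6-methylated adenosines lie in HEK293T and MEF transcripts, and the level, ribosome occupancy and stability of HEK293T transcripts with and without PCIF1, the enzyme that the study's title names as the m6Am methyltransferase. The m6A lists held 43663 sites in WT HEK293T, 40768 and 47644 in KO replicates 1 and 2, and 37141 and 38455 in MEF replicates 1 and 2. The median read number at a site was 30 in WT and 37 and 42 in the KO libraries. The input libraries held 5960674 and 5386307 counts in WT replicates 1 and 2 and 5842630, 5638480 and 4511687 in KO replicates 1 to 3. Over the 785 listed genes, the ribosome-protected fragment libraries held 17665 and 61816 counts in WT and 124580, 46193 and 58325 in KO. A count of 3 corresponded to at most 0.665 CPM in the input and to 170 CPM of the listed genes in WT fragment replicate 1. Pairs of replicates differed by more than sampling noise in both tables, with chi-square over degrees of freedom from 2.92 to 19.9, so no library was taken for another deposited again. That does not show that the libraries are independent replicates.

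The strict m6Am regions lay mostly at annotated gene starts. Of 2360 regions, 78.7% (exact interval 77.0 to 80.4%) lay within 50 nt of an annotated gene start on the same strand, against 5.13% within 50 nt of a gene's opposite end, and 66.4% covered the start itself. They named 1838 genes, of which 1751 code for protein, or 8.73% of the 20050 protein-coding genes of the reference. By the authors' score, the highest region with a gene covered the start of BUB1, a kinase of the spindle checkpoint (GRCh38 chromosome 2, 110677951 to 110678100, score 5.23). It was followed by FTH1, the ferritin heavy chain (chromosome 11, 61967501 to 61967700, 5.23), ETFA, an electron transfer flavoprotein subunit (chromosome 15, 76311301 to 76311500, 5.13), and COX8A, a subunit of cytochrome c oxidase (chromosome 11, 63974551 to 63974700, 5.11). SNRPF, a core spliceosomal protein (5.09), and MRFAP1 (5.07) were also among the 10 highest, and the other 4 had no gene start within 50 nt. The list is a single one, with no replicate. How its regions were picked is not stated, and if closeness to a start was required, the share near starts would follow by construction.

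Genes of the respiratory chain and of the translation apparatus carried m6Am regions more often than other genes with m6A sites. Only those of the respiratory chain lay beyond the spread of random lists matched on reads. Of 60 nuclear oxidative phosphorylation genes with an m6A site, 33 (55.0%, exact interval 41.6 to 67.9%) had a region, against 15.5% of the other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 13 lists, p = 3.39e-11). Examples are COX8A (score 5.11), NDUFS1, the largest core subunit of complex I (4.64), and CYCS, cytochrome c (4.43). Among ribosomal proteins 26 of 66 did (39.4%, 27.6 to 52.2%, adjusted p = 1.89e-05), such as RPL36 (4.27) and RPL23A (4.15). Other TOP mRNAs, named for a pyrimidine tract at their start, had 8 of 17 (47.1%, 23.0 to 72.2%, adjusted p = 0.00769), among them TPT1 (3.56) and EEF1D (3.32). The base at the start was not checked, so a region does not show m6Am at such a tract. Cell cycle genes had 10 of 24 (41.7%, 22.1 to 63.4%, adjusted p = 0.00769), with BUB1 (5.23), AURKB, a mitotic kinase (4.66), and MCM7, part of the replicative helicase (3.66). The test was added after these shares had been seen. Against random lists matched on reads at m6A sites the shares lay at percentile 100 (oxidative phosphorylation), 97.6 (ribosomal proteins), 97.8 (other TOP mRNAs) and 98.6 (cell cycle), and lists matched to the ribosomal proteins had a median of 28.8%, against 15.7% of all genes with an m6A site.

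The other 9 lists tested were not called, with adjusted p from 0.247 to 1. Their shares were 33.3% of 12 heat shock genes, 30% of 20 genes of the integrated stress response, 29.4% of 17 cap methylation and binding genes and 25% of 24 m6A and m6Am enzymes and readers. Replication-dependent histones had 22.2% of 9, cholesterol synthesis 20% of 15, decapping and decay 18.5% of 27, p53 targets 18.2% of 11 and neural markers 16.7% of 6. Within the enzymes and readers, METTL3, the catalytic subunit of the m6A writer, had a region at its start (chromosome 14, 21511251 to 21511350, score 3.65). PCIF1, METTL14, FTO and YTHDF2 had none named. Over all protein-coding members, with or without an m6A site, 1 of 24 interferon-stimulated genes had a region. Of 14 fibroblast and 11 blood and endothelial markers none did, against 8.73% of all protein-coding genes. In WT only 1, 2 and 0 members of these lists had an m6A site, so their counts say little on m6Am.

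**Figure D1:**
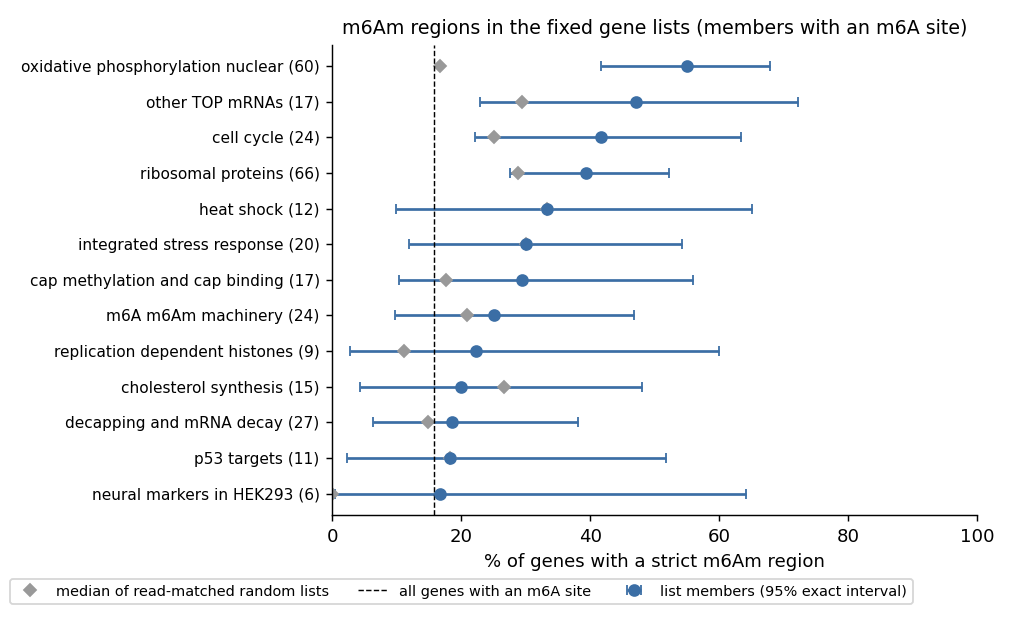
Percent of genes with a strict m6Am region (horizontal axis) in each gene list, over members with an m6A site (number in brackets), with exact 95% intervals as bars. Diamonds give the median of random lists matched on reads and the dashed line all genes with an m6A site (15.7%); oxidative phosphorylation genes lie farthest to the right, at 55.0%.

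The m6A lists of WT and KO HEK293T cells address whether internal m6A depends on PCIF1. The span of PCIF1 itself held 2 m6A sites in WT and 1 in each KO library. Sites were named without strand, so these sites do not settle whether its transcript was read in the KO cells. METTL3 had 4 sites in each of the 3 libraries, METTL14 had 6, 8 and 4, FTO, an m6A and m6Am demethylase, had 5, 4 and 1, YTHDF2, an m6A reader, had 18, 16 and 19, and DCP2, the decapping enzyme, had 7, 4 and 7 (WT, then KO replicates 1 and 2). Among WT sites lying in 1 gene, those with the most substituted reads were in IRS4 (chromosome X, 108733372, 198 of 1463 reads, 13.5%), ACTG1 (chromosome 17, 81510684, 152 of 1294, 11.7%) and SCAMP4 (chromosome 19, 1925608, 130 of 315, 41.3%). In KO replicate 2 the same 3 positions had 14.5%, 10.9% and 41.1%. EIF4EBP1, a repressor of cap-dependent translation, was also among the 10 highest in WT (chromosome 8, 38060055, 112 of 316, 35.4%).

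Of the WT sites, 37.4% (exact interval 37.0 to 37.9%) were listed in KO replicate 1 and 42.4% (42.0 to 42.9%) in KO replicate 2, against 43.9% (43.4 to 44.4%) of KO replicate 1 sites in KO replicate 2. In the reverse direction, 37.6% (37.1 to 38.0%) of KO replicate 2 sites were listed in KO replicate 1. The share thus depends on the list searched, and KO replicate 2 has the longest one. The lists overlapped far more where reads were many: of the 3273 WT sites with at least 10 substituted reads, 91.1% and 95% were listed in the KO libraries, against 12.6% and 14.4% of those with 2. By gene, 82.7% and 85.7% of WT genes with a site had a site in KO replicates 1 and 2. Between the KO libraries the shares were 86.2% (KO replicate 1 genes in KO replicate 2) and 82.4% (the reverse). At the 11576 sites in all 3 lists, 6.46% (6.42 to 6.50%) of reads carried the substitution in WT, 6.43% (6.39 to 6.47%) in KO replicate 1 and 6.30% (6.27 to 6.34%) in KO replicate 2. Positions that lost their substitutions in KO are left out of these sites, so the shares cannot show such a loss. The GGAC core made up 34.0%, 34.4% and 34.4% of sites. With 1 WT library the genotype was not tested.

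Near gene starts the WT list held a larger share of its sites than the KO lists, and the difference was wider inside the m6Am regions. In WT 0.751% of sites (exact interval 0.672 to 0.837%) lay within 50 nt of a start, against 0.640% (0.565 to 0.722%) and 0.565% (0.499 to 0.636%) in KO replicates 1 and 2. Inside m6Am regions lay 101 WT sites (0.231%, 0.188 to 0.281%), against 37 (0.0908%, 0.0639 to 0.125%) and 45 (0.0945%, 0.0689 to 0.126%). The share was 2.49 times (interval 1.86 to 3.34) that of both KO lists together, while near starts outside the regions the ratio was 1.17 (1.01 to 1.36). Of the 161 positions inside regions in any list, 86 were listed in WT alone, 60 in KO alone and 15 in WT and a KO library. The intervals cover counting error only, and no second WT library was at hand. Per the labels, the description of the WT miCLIP sample names the region list, and how the regions were picked is not stated. If they were picked for signal in this library, more WT sites inside them would follow by construction.

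**Figure D2:**
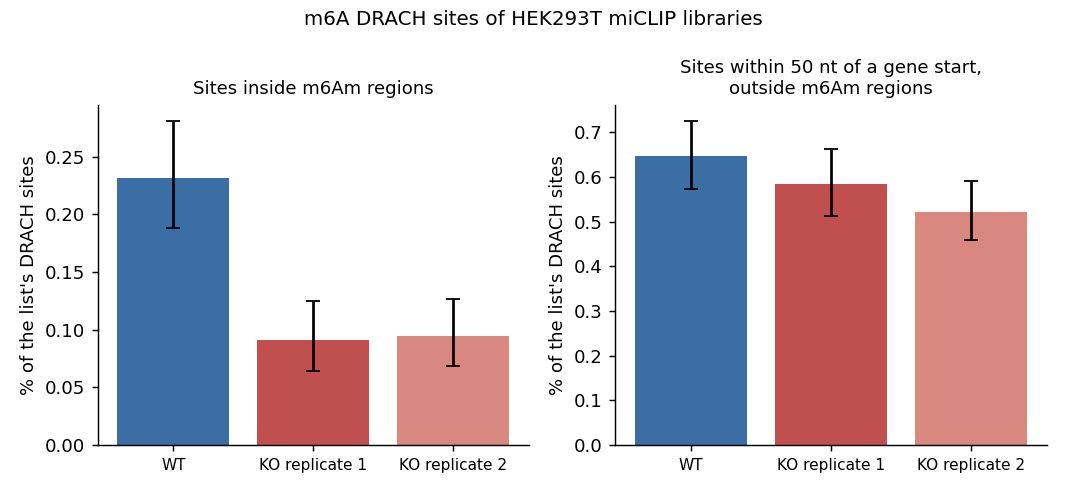
Percent of each library's m6A DRACH sites inside strict m6Am regions (left) and within 50 nt of a gene start outside them (right), with exact 95% intervals, for 1 WT and 2 KO libraries. The left bars are 0.231%, 0.0908% and 0.0945%. The regions may have been picked for signal in the same WT library.

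In MEF the lists of both replicates shared sites to a similar extent as the human ones. Of replicate 1 sites, 43.0% (exact interval 42.5 to 43.5%) were listed in replicate 2, and of the 3060 replicate 1 sites with at least 10 substituted reads, 94.5% were. The GGAC core made up 35.8% and 35.2% of sites. The highest site on chromosome 10 (mm10, 81182261) had 9.07% and 9.04% of reads substituted. Mouse genes were not named here.

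Transcripts that the authors class as m6Am were more abundant in WT cells than other classed transcripts. The 501 m6Am genes had a median of 7.61 log2 CPM in WT input, against 6.61 for the 895 others, a difference of 0.997 (replicate 1 alone 1.01, replicate 2 alone 1.04). The difference was 0.23 among the genes of the efficiency table (percentile 97.1 of random lists), 0.47 among those measured by SLAM-seq (percentile 91) and, with A starts alone as the background, 0.66. The pooled value thus also reflects the make-up of the tables. If the m6Am class needed a region detected from reads, abundant transcripts would enter it more easily. Whether the difference arose in that way was not tested. The others had a median of 7.52 in the efficiency table (n = 349) and 5.73 in the SLAM-seq table (n = 561), and 416 of the m6Am genes are of the former. WT translational efficiency was apart by -0.14 in median log2 between 416 m6Am and 349 other genes, with -0.18 in replicate 1 and 0.08 in replicate 2, so the libraries gave opposite directions.

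Loss of PCIF1 left the input RNA of nearly all genes within the spread between libraries. The RNA level of PCIF1 is not analysed here, so the counts do not check the genotype labels. Of 14629 genes, edgeR's quasi-likelihood test called 5 at an adjusted p under the threshold, all lower in KO. At an unadjusted p under 0.05 there were 1360 genes, 454 higher and 906 lower, and DESeq2 called 15. None of the 5 is named in the files. Among those with a mean of at least 5 CPM the largest falls were in a pair of genes: ENSG00000233922.2 fell by 2.08 on the log2 scale (SE 0.22, edgeR adjusted p = 0.00622), from 29.7 ± 4.17 CPM in WT (SD, n = 2) to 6.97 ± 1.29 in KO (SD, n = 3). ENSG00000115266.11 fell by 1.90 (SE 0.25, edgeR adjusted p = 0.0266), from 18.1 ± 1.496 to 4.75 ± 1.40 CPM. A gene of lower mean level fell by 3.43, and the smallest fall was 0.97. Without KO replicates 1, 2 and 3, 2, 3 and 3 of the 5 stayed called. Leaving out a WT library leaves 1 in that group, so those fits take their spread from the KO libraries alone, and their calls say nothing on how well the 5 hold. The count itself moved with the libraries, to 53 without WT replicate 1, 1912 without WT replicate 2, and 2, 8 and 3 without KO replicates 1, 2 and 3. WT replicate 1 stood apart from the other 4 input libraries on the first principal component (40.2 against -2.22 to -16.3, 41.7% of variance).

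Among named genes none passed edgeR's test over all genes. FTO was at -0.11 (SE 0.13, edgeR adjusted p = 0.837) and turned to 0.15 without WT replicate 1. DCP2 was at 0.44 (SE 0.16, edgeR adjusted p = 0.513) and IGF2BP1, an m6A reader, at -0.36 (SE 0.10, edgeR adjusted p = 0.449). Of the 3 tested enzymes and readers, edgeR called IGF2BP1 alone when adjusted over the list alone (adjusted p = 0.0128). That adjustment covers the 3 genes only, and neither the number of lists nor that of comparisons. Without WT replicate 2, against the other WT library alone and with spread from the KO libraries, edgeR called DCP2 (0.76, adjusted p = 3.85e-05) and IGF2BP1 (-0.51, adjusted p = 4.39e-07), and with all 5 libraries and no filter it also called IGF2BP1 (-0.36, adjusted p = 0.0173). Over the alternatives edgeR's and DESeq2's adjusted p ranged from 3.85e-05 to 0.942 for DCP2 (log2 fold change 0.20 to 0.76) and from 4.39e-07 to 0.909 for IGF2BP1 (-0.51 to -0.15). The named gene nearest to the threshold, chosen after its values were seen, was RNF213, a large ubiquitin ligase, at -0.60 (SE 0.10, edgeR adjusted p = 0.0955).

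Ribosomal protein mRNAs were slightly higher in KO input, 34 of 36 members with a median log2 fold change of 0.15, and camera called the list (adjusted p = 7.14e-05; adjusted p = 0.615 with an estimated correlation). RPL31 (0.30, SE 0.11), RPL24 (0.28, SE 0.11) and RPL35 (0.27, SE 0.11) had the smallest p among the members, none called when adjusted over the list alone. Oxidative phosphorylation genes had 28 of 31 higher with a median of 0.10 (camera adjusted p = 0.00417; adjusted p = 0.615 with an estimated correlation), with UQCRB, a complex III subunit, at 0.53 (SE 0.16). Replication-dependent histones had 25 of 28 higher with a median of 0.11 (camera adjusted p = 0.0339; adjusted p = 0.615 with an estimated correlation). Without WT replicate 1 the medians of the 3 lists were 0.05, 0.01 and 0.00 and limma's camera called none. Without KO replicate 3 they were 0.09, 0.07 and 0.03, with ribosomal proteins alone called. Without WT replicate 2 they were 0.28, 0.27 and 0.26, and without KO replicate 1 the histone median was 0.17. Over the alternatives camera's adjusted p ranged from 1.94e-06 to 0.615 for ribosomal proteins, from 0.000295 to 0.889 for oxidative phosphorylation and from 2.16e-05 to 0.877 for histones. Of the genes of these lists named by the rule, edgeR called RPL24 (0.45), RPL35 (0.42), UQCRB (0.82), ATP5F1 (0.50), ATP5C1 (0.70), HIST1H2AG (0.38), HIST1H3B (0.38) and HIST1H3F (0.53) without WT replicate 2. Their values without WT replicate 1 were 0.15, 0.16, 0.31, 0.24, 0.16, 0.10, 0.05 and 0.10 in the same order.

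Camera called no other list in the input. Of 16 cell cycle genes 11 were higher (median 0.05), with CDK1, the mitotic kinase, at 0.58 (SE 0.20). Of 6 other TOP mRNAs 5 were higher (0.03), with EIF3E, an initiation factor subunit, at 0.53 (SE 0.20). Of 8 heat shock genes 6 were higher (0.10), with HSP90AA1 at 0.32 (SE 0.14). Cap methylation and binding had 1 of 7 higher (-0.01, but 0.01 with DESeq2's size factors or without KO replicate 1 and 0.09 without WT replicate 1) and decapping and decay 3 of 6 (0.04). Too few for camera were the integrated stress response with 3 of 3 higher (0.03), cholesterol synthesis with 2 of 4 (0.05) and p53 targets with MDM2 alone at -0.07 (SE 0.14). Interferon-stimulated genes, mitochondrially encoded genes and neural, fibroblast, blood and endothelial markers had no named member tested. Adjusted over the list alone, edgeR called no member of these lists. Over all genes edgeR called CDK1 (1.002), EIF3E (0.998), HSP90AA1 (0.63), HSPH1 (0.62) and EIF4A2 (0.47) as higher without WT replicate 2, where MDM2 turned to 0.17. Without WT replicate 1 CDK1 was at 0.27, EIF3E at 0.19, HSP90AA1 at 0.09, HSPH1 at 0.12 and EIF4A2 at 0.17. The fit without WT replicate 2 also called CNOT1 (-0.49), EIF4EBP2 (-0.45), PABPC1 (-0.34), MCM4 (-0.33), LARP1 (-0.28) and HSPA5 (-0.27) as lower, and without WT replicate 1 each turned positive (0.10, 0.09, 0.04, 0.08, 0.15 and 0.01).

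The m6Am genes moved little in RNA level. Their median log2 fold change was 0.04 over 501 genes, against -0.01 over 895 others, a difference of 0.05 (camera p = 0.0319; p = 0.151 with an estimated correlation). Their median lay at percentile 100 of random lists matched on level, which spread from -0.01 to 0.01, and at percentile 99.96 against A starts alone. Against A starts alone, an alternative chosen after seeing the data, the difference was 0.03 (n = 501 and n = 389 genes, limma's camera p = 0.402). These values pool genes of the efficiency and SLAM-seq tables. Within the efficiency table alone the median RNA change was 0.0385 for 416 m6Am genes and 0.0426 for 201 A starts. C, G and T starts there had -0.0156, 0.0144 and 0.0001. In that table m6Am genes were thus not above A starts. Leaving out WT replicate 2 (0.06, limma's camera p = 0.0719), KO replicate 1 (0.04, p = 0.0629) or KO replicate 3 (0.03, p = 0.0891) ended the call over these genes (n = 501 with m6Am). Without WT replicate 1 the difference was 0.03 and still called at the preset correlation (n = 501 and n = 895 genes, limma's camera p = 0.0222; p = 0.246 with an estimated correlation), and over the alternatives limma's camera p ranged from 0.00493 to 0.402.

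**Figure D3:**
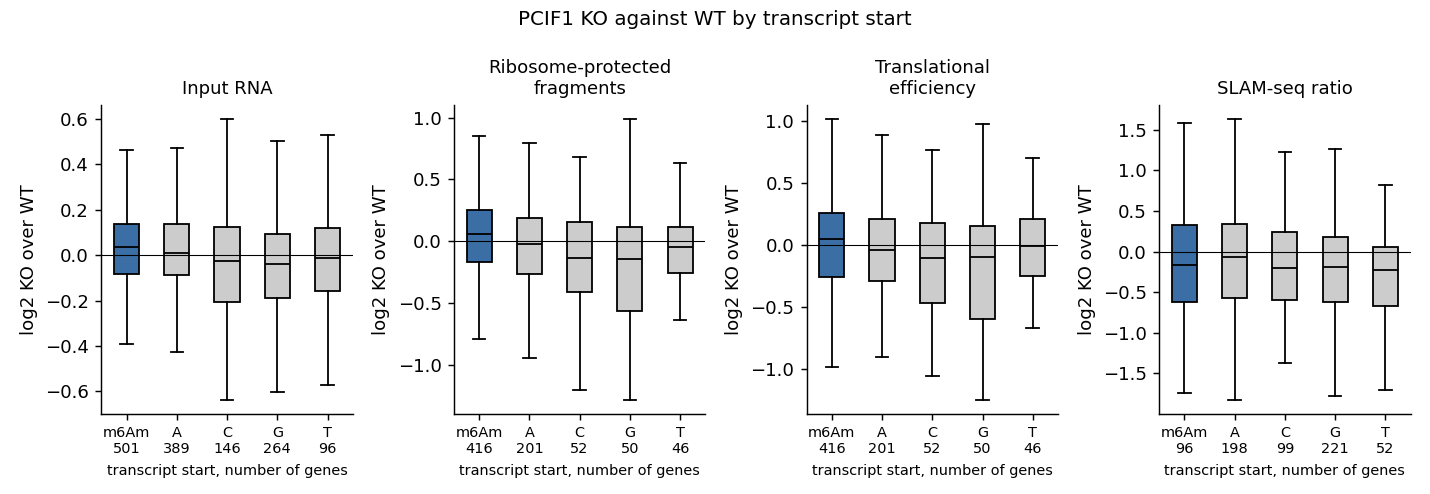
Log2 KO over WT by the authors' transcript start class (m6Am, A, C, G, T, with the number of genes) for input RNA, ribosome-protected fragments, translational efficiency and the authors' SLAM-seq ratio. Boxes span quartiles with the median, and whiskers reach the last gene within 1.5 box lengths; m6Am medians are 0.04, 0.06, 0.05 and -0.17.

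In ribosome-protected fragments no gene passed edgeR's test over the 785 listed genes: 0 were called, 30 had an unadjusted p under 0.05 (16 higher and 14 lower, but 5 and 13 with DESeq2) and DESeq2 called 0. VIM, the intermediate filament vimentin, had 2329 ± 254 CPM of the listed genes in WT (SD, n = 2) and 4034 ± 390 in KO (SD, n = 3), a log2 fold change of 0.78 (SE 0.24, edgeR adjusted p = 0.915). ATF4, the transcription factor of the integrated stress response, had 730 ± 272 and 342 ± 59.9, a log2 fold change of -1.15 (SE 0.38, adjusted p = 0.915). When adjusted over the list alone, edgeR called VIM among 6 other TOP mRNAs (adjusted p = 0.0233) and ATF4 among 3 stress response genes (adjusted p = 0.0185). That adjustment covers the 6 or 3 listed members only, and neither the number of lists nor that of comparisons. ATF4 was at -0.62 without WT replicate 2, and at -1.39 to -0.62 over the alternatives. In WT replicate 1 ATF4 had 537 CPM, as did NDUFA2, which is the lowest count of that library, 10. A count limit on WT alone can favour listed genes whose WT count is high by chance. Without WT replicate 2 edgeR called 3 genes, and without KO replicate 1 or KO replicate 3 it called 1.

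Fragments of ribosomal proteins were higher in KO as a list, 28 of 36 with a median of 0.20 (camera adjusted p = 0.00248; adjusted p = 0.181 with an estimated correlation). FAU, a ribosomal protein fused to a ubiquitin-like domain, was at 0.96 (SE 0.32) and RPLP1 at 0.60 (SE 0.30; 0.28 to 0.86 over the alternatives), neither called when adjusted over the list alone. Without WT replicate 1 the median was 0.17 and the list was not called (limma's camera adjusted p = 0.131), and over the alternatives camera's adjusted p ranged from 0.00230 to 0.181. At a mean of at least 50 counts, an alternative chosen after seeing the data, the median was 0.09 and the list was not called (limma's camera adjusted p = 0.111). Camera called no other list. Oxidative phosphorylation had 19 of 30 higher (0.18; 0.02 to 0.19 over the alternatives), with UQCRC1 at 0.80 (SE 0.30) and NDUFA2 at -1.04 (SE 0.60). Histones had 17 of 28 (0.08), with a median of -0.07 without WT replicate 1, of -0.01 at a mean of at least 50 counts and of 0.37 without WT replicate 2, where limma's camera called the list (adjusted p = 0.0370, range over the alternatives 0.0370 to 0.981). The cell cycle had 11 of 16 (0.13; 0.02 to 0.14 over the alternatives), other TOP mRNAs 5 of 6 (0.23), heat shock 2 of 8 (-0.10, but 0.18 without WT replicate 2) and cap methylation and binding 3 of 5 (0.34, with EIF4G1 at 0.50, SE 0.30). Smaller lists had 2 of 3 decay genes, 2 of 3 stress response genes, 1 of 2 cholesterol synthesis genes and 0 of 2 enzymes and readers higher.

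**Figure D4:**
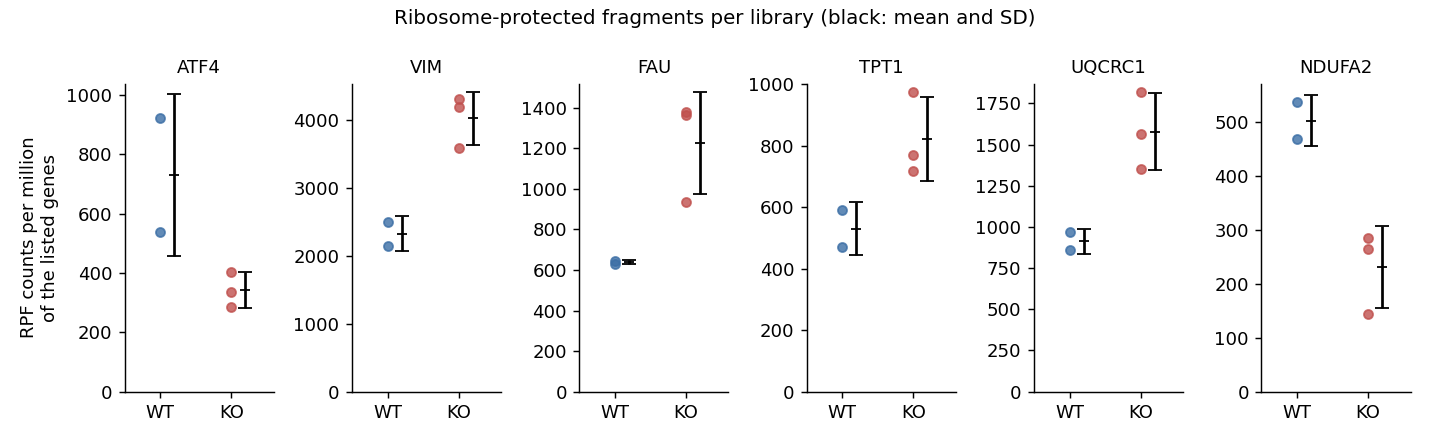
Ribosome-protected fragments of 6 genes, chosen after their values were seen, in CPM of the listed genes (vertical axes) for each WT (blue) and KO (red) library, with the mean and SD in black. ATF4 averages 730 in WT and 342 in KO and VIM 2329 and 4034, and none of the 6 passed the test over all listed genes. In WT replicate 1 ATF4 and NDUFA2 stand at the lowest count of that library, 10.

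The m6Am genes had a median log2 fold change of 0.06 in fragments over 416 genes, against -0.05 over 349 others, a difference of 0.11 (camera p = 0.0253; p = 0.0988 with an estimated correlation). Their median lay at percentile 98.2 of random lists matched on level. Without WT replicate 1 the difference was 0.00 (limma's camera p = 0.748), without WT replicate 2 it was 0.26 (p = 0.00132), and without KO replicate 1 it was 0.11 (p = 0.0567; n = 416 and n = 349 genes in each). WT replicate 1 has the fewest counts over the listed genes: 116 of its 785 genes stood at exactly 10 counts, the lowest value that either WT library holds, against 4 in WT replicate 2. Among genes of at least 50 counts on average, an alternative chosen after seeing the data, the difference was 0.03 (n = 254 and n = 154 genes, limma's camera p = 0.863), and over the alternatives the p ranged from 0.00132 to 0.863.

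**Figure D5:**
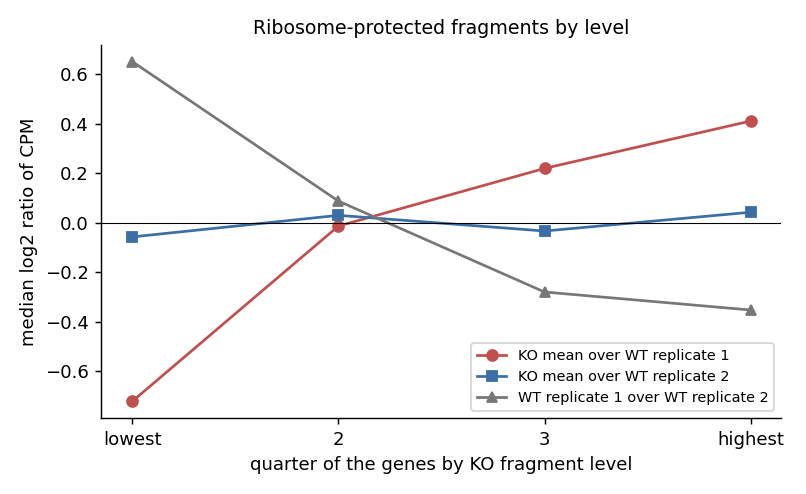
Median log2 ratio of fragment CPM (vertical axis) in 4 groups of the listed genes by KO level (horizontal axis), for the KO mean over each WT library and for WT replicate 1 over WT replicate 2. KO over WT replicate 1 goes from -0.72 in the lowest group to 0.41 in the highest, and KO over WT replicate 2 from -0.06 to 0.04.

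Translational efficiency, fragments relative to input, was compared to ask whether m6Am alters translation. ATF4 had an interaction of -1.21 (SE 0.29, edgeR adjusted p = 0.483) and VIM 0.78 (SE 0.20, adjusted p = 0.483), with input log2 fold changes of 0.06 (SE 0.08) and 0.01 (SE 0.09). In WT replicate 1 the fragments of ATF4 stood at the lowest count of that library, 10. edgeR called 0 of 785 genes, 53 had an unadjusted p under 0.05 (31 higher and 22 lower, but 25 and 28 with DESeq2's size factors and 28 and 42 with DESeq2), and DESeq2 called 2, ATF4 (-1.24, DESeq2 adjusted p = 0.0225) and VIM (0.73, DESeq2 adjusted p = 0.0452). Over the alternatives the adjusted p ranged from 0.0225 to 0.933 for ATF4 and from 0.0452 to 0.933 for VIM. When adjusted over the list alone, edgeR's interaction called both (adjusted p = 0.00250 among stress response genes and adjusted p = 0.00893 among other TOP mRNAs). Here too the adjustment covers neither the number of lists nor that of comparisons. Without WT replicate 2, 14 genes were called (6 higher, 8 lower) and ATF4 was at -0.64 and VIM at 0.98. The authors' deposited table lists the same 2 genes at an adjusted p under 0.05, and its log2 fold changes for 765 genes equal those of the DESeq2 interaction within 0.001.

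Other genes of the authors' deposited table with large values were SPEN, a transcriptional repressor (1.08), FARSA, a subunit of phenylalanyl-tRNA synthetase (1.05), PYGL, liver glycogen phosphorylase (1.01), DNAAF5 (0.88) and FAU (0.87). At its low end the authors' deposited table had MADD (-1.04), RABL6 (-1.01), COLGALT1, a collagen galactosyltransferase (-0.81), and RIC8A (-0.80). In the interaction fit NDUFA2 was at -1.15 (SE 0.41), CDK1 at -1.13 (SE 0.45), UPF1, the helicase of nonsense-mediated decay, at 0.77 (SE 0.34; 0.04 to 1.24 over the alternatives) and TPT1 at 0.66 (SE 0.29), none called when adjusted over its list alone. Camera called no list. Members with a higher efficiency were 28 of 36 ribosomal proteins (median 0.10), 18 of 30 oxidative phosphorylation genes (0.05, but -0.23 without WT replicate 2), 14 of 28 histones (-0.00, but 0.12 without WT replicate 2 and 0.08 without KO replicate 3), 9 of 16 cell cycle genes (0.14), 4 of 6 other TOP mRNAs (0.23), 1 of 8 heat shock genes (-0.26, but 0.00 without WT replicate 2) and 3 of 5 cap genes (0.39). Smaller lists had 2 of 3 decay genes, 2 of 3 stress response genes, 2 of 2 enzymes and readers and 0 of 2 cholesterol synthesis genes higher.

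The m6Am genes had a median efficiency change of 0.05 against -0.04 for the others, a difference of 0.09 over 416 and 349 genes (camera p = 0.125; p = 0.118 with an estimated correlation), at percentile 82.2 of matched lists. Without WT replicate 1 the difference was 0.00 (limma's camera p = 0.494) and without WT replicate 2 it was 0.25 (p = 0.00726; n = 416 and n = 349 genes), the ends of the range over the alternatives. In the authors' deposited table the medians were 0.03 for m6Am, -0.06 for A, -0.13 for C, -0.11 for G and -0.04 for T starts.

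SLAM-seq asks whether transcripts lose their label faster without PCIF1. In the authors' deposited table, 61.5% of the 96 m6Am genes and 60.2% of the 570 others had a KO over WT ratio below 1, with the same median log2 ratio of -0.17. The difference of medians was -0.00 (bootstrap interval -0.16 to 0.15), and the m6Am median lay at percentile 58.2 of lists matched on input level. A starts without m6Am had a median of -0.07 and C, G and T starts -0.21, -0.19 and -0.22; against A starts alone m6Am genes were lower by -0.10, at percentile 6.95. Among genes of at least median input level, the authors' deposited table had its lowest ratios in SLC11A2, an iron transporter (0.164), ZNF576 (0.249), KMT2C, a histone methyltransferase (0.252), TBL1X (0.260) and SNX27 (0.272). Its highest were GSTZ1 (3.11), FHL1 (2.997), LSR (2.78), BIRC5, the apoptosis inhibitor survivin (2.68), and AGAP3 (2.54). FTO had 1.07 and DCP2 0.902 in the authors' deposited table. Of the lists, 2 ribosomal proteins, RPL14 and RPL37A, had log2 ratios of 0.04 and 0.86, MDM2 had -0.81 and SDHC -0.18. Cap genes had EIF4EBP2 at -0.46 and EIF4G3 at 0.28, decay genes CNOT6 at -0.57 and CNOT8 at 0.26, and cholesterol synthesis FDFT1 at 1.46 and SREBF2 at -0.35. Each genotype and time has 1 library and no error is given, so no gene was tested, and the interval and percentiles cover the spread over genes alone. Ratios of different quantities (half-life, label kept) would read in the same direction only if the authors divided a measure of stability.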

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

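Of 145 alternative values for the comparisons, 75 were counted as the same, 41 moved, 25 lost and 2 gained a call, and 2 were counted as a change of sign. SLAM-seq differences of 0.00411 (against genes with an m6A site) and 0.00357 (below the median input level) were counted as the same. Their sign is opposite to the main value of -0.00319, but they lie within its bootstrap interval. Of 174 for gene lists, 161 stayed the same, 12 changed sign and 1 gained a call (histones in fragments, 0.372 without WT replicate 2). Among 891 alternatives for named genes, 24 brought a call and 48 a change of sign. The cause was not tested for any value below unless stated. Alternatives on SLAM-seq time points, a pseudocount, untranslated and coding parts and mouse genes were not run, as the files used here give no such values, and the filters that remove no gene from the fragment table were not run.

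Allowing 5 nt raised the site overlap to 38.1% (WT in KO replicate 1), 43.1% (WT in KO replicate 2), 44.5% (KO replicate 1 in 2) and 43.7% (MEF). With at least the median number of substituted reads it was 50.5%, 57.2%, 56.4% and 54.7%, and by gene 82.7%, 85.7% and 86.2% for the human pairs. Within 20 nt of a start lay 0.325%, 0.255% and 0.233% of WT, KO replicate 1 and KO replicate 2 sites, and within 100 nt 1.51%, 1.37% and 1.35%, by construction of the window. Of KO replicate 1 sites with at least the median number of substituted reads, 0.0515% lay in m6Am regions. Of the regions, 74.9% lay within 20 nt and 80.5% within 100 nt of a start, and 74.9% within 50 nt of a protein-coding one.

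With limma's correlation estimated, values kept and calls ended: the m6Am shift in RNA was 0.0476 (camera p = 0.151) and in fragments 0.11 (p = 0.0988), and list medians were 0.15 (ribosomal proteins), 0.10 (oxidative phosphorylation) and 0.11 (histones), each at adjusted p = 0.615, and 0.20 (ribosomal proteins in fragments, adjusted p = 0.181). Against A starts alone, chosen after seeing the data, the shift was 0.0265 in RNA (n = 501 and n = 389 genes, camera p = 0.402) and 0.0751 in fragments (n = 416 and n = 201, p = 0.180). At a mean of at least 50 counts, also chosen after seeing the data, the fragment shift was 0.0344 and the ribosomal protein median 0.0935, neither called.

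DESeq2 called 15 genes in RNA and 2 in efficiency, and edgeR called 152 in RNA without a filter. The replicate number is all that libraries share across genotypes: deviations of same-numbered libraries correlated at 0.161 and -0.003 in the input and 0.195 and 0.209 in fragments. With a replicate block edgeR called 3 genes in RNA and 6 in fragments. With the replicate block the list medians in RNA were 0.0863 (ribosomal proteins), 0.0646 (oxidative phosphorylation) and 0.00495 (histones), and the m6Am shift was 0.0315, none called by limma's camera, while the shift in efficiency was 0.0849 and called (n = 416 and n = 349 genes, p = 0.0353; p = 0.183 with an estimated correlation).

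Without a WT library 1 is left in that group, and the spread comes from the KO libraries alone, so calls gained or kept in those fits carry no weight of their own. Leaving out 1 library gave from 2 (without KO replicate 1) to 1912 (without WT replicate 2) calls in RNA, 0 to 3 in fragments and 0 to 14 in efficiency. The m6Am shift went from 0.0286 to 0.0556 in RNA, from 0.00388 to 0.258 in fragments and from 0.00425 to 0.2499 in efficiency. List medians went from 0.0545 to 0.280 (ribosomal proteins), 0.0146 to 0.274 (oxidative phosphorylation) and 0.000648 to 0.258 (histones) in RNA, and from 0.174 to 0.260 for ribosomal proteins in fragments. Except for the counts, the low ends are without WT replicate 1 and the high ends without WT replicate 2.

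The WT difference of m6Am genes in RNA level was 0.83 against genes with an m6A site, 0.96 at a mean of at least 5 CPM and 1.04 in WT replicate 2 alone. Chosen after seeing the data, it was 0.23 for genes of the efficiency table, 0.47 for those of SLAM-seq and 0.66 against A starts. The WT difference in efficiency turned to 0.0281 against genes with an m6A site and to 0.0817 in WT replicate 2 alone.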

Other observations

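Of the tests below, those on fragments by level and on sites in m6Am regions were chosen only after the result was seen, while those on ribosomal protein and oxidative phosphorylation mRNAs and on SLAM-seq were written down before their own values were computed, although single genes of those lists had been seen by library.

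Among m6A sites in all 3 HEK293T lists with at least 100 reads per library, the sites below had some of the largest differences from WT shared by both KO libraries. Such a ranking also picks extremes of the 1 WT library, and the shares rest on few substituted reads (2.26% of 221 reads at BIRC5 in WT). At ICMT, which methylates the carboxyl end of prenylated proteins (chromosome 1, 6224026), 6.52% of reads carried the substitution in WT and 1.72% and 1.86% in KO. UCHL5, a proteasome-bound deubiquitinase, had 9.09% in WT and 2.65% and 2.60% in KO. In the other direction lay POGZ, a chromatin protein (3.45% in WT, 16.5% and 11.1% in KO), and BIRC5 (2.26%, then 7.69% and 7.56%). Of the 10 such sites with the largest differences, 7 were higher in KO and 3 lower, and the 2 largest, higher in KO, lay in no single named gene. Over all 11576 shared sites the log2 ratio of shares had quartiles of -0.49 and 0.49 for KO replicate 1 over WT. Between the KO libraries (replicate 2 over 1) they were -0.55 and 0.43, so the spread was as wide without a difference of genotype. With 1 WT library no test was run.

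The genes with the most m6A sites were SPEN (87 in WT, 60 and 87 in KO), MKI67, a marker of proliferating cells (80, 54 and 83), IRS4, an adaptor of insulin signalling (69, 58 and 60), SON (57, 51 and 67), SRRM2 (53, 47 and 64) and TUG1, a long noncoding RNA (52, 46 and 53). DICER1, which cuts microRNA precursors, made up 10.2% of the fragment counts of KO replicate 2, at 113180 CPM of the listed genes against 1149 to 11556 in the other libraries.

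Ribosomal protein and oxidative phosphorylation mRNAs were higher in the KO input. WT replicate 1 standing apart from the other input libraries is a candidate explanation: against WT replicate 2 alone the median difference over both lists was 0.0229 (bootstrap interval 0.00 to 0.06), against 0.25 for WT replicate 1. That met the limit of 0.05 set for it, but the interval spans the limit and ribosomal proteins alone gave 0.053, so a small rise stays open. As a biological alternative, members with an m6Am start were 0.0675 higher than the others (0.00 to 0.11), past the limit set. A demand added afterwards, that the same hold against WT replicate 2 alone, was not met (0.04, -0.02 to 0.08), and the question stays open.

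In fragments, genes of low KO level were lower in KO than in WT, and m6Am genes were higher than others. The limit of 10 counts in both WT libraries may account for it. WT replicate 1, with the fewest counts over the listed genes, reaches the limit at low genes only when its count is high by chance. Between the WT libraries themselves the lowest group of genes by KO level exceeded the highest by 1.004 (bootstrap interval 0.91 to 1.15). A loss of ribosome occupancy in KO would appear against WT replicate 2 as well, where the same contrast was -0.0998 (-0.20 to -0.01). Grouping by KO level by itself lowers KO over WT in the lowest group, so this contrast includes that bias. Of the lowest group 40.1% and of the highest 60.6% were m6Am genes, so the limit could also raise their median.

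WT had more m6A sites than KO inside m6Am regions. The number of sites or reads in the WT list may not explain it, as the share of sites was 2.49 times that of KO and the WT list is neither the largest nor the deepest. Regions picked for signal in the same WT library would raise WT inside them alone, and near starts outside them the ratio was 1.17 (1.01 to 1.36), under the limit set for it, which the interval spans. Loss of m6Am from KO cells would give the same 2 values, so the data cannot tell these apart. For SLAM-seq, m6Am genes below the median input level lay at percentile 52.7 of matched lists, with a difference of 0.00 (bootstrap interval -0.17 to 0.20) that leaves effects of either sign open, and the demand on that spread was added after the value was seen.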
